A study of Arabidopsis thaliana with 44 samples.

How the data were processed

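Messenger RNA was profiled on 44 single-colour Affymetrix arrays from whole seedlings of Arabidopsis thaliana, in 22 groups with 2 replicates each. Per the labels, each array holds RNA pooled from many plants, and the labels do not say whether the replicates were separate cultures, so p-values here measure the spread between these samples. The series text states that HZE was given in 2 runs without saying which replicate came from which, so the spread between HZE replicates may or may not hold a difference between runs. The groups were WT and atm-1, a mutant of the DNA damage kinase ATM, after 100 Gy of gamma rays or 30 Gy of HZE (accelerated iron nuclei), with unirradiated groups of both genotypes on 2 days. WT was sampled at 1.5, 3, 6, 12 and 24 h after both radiations, and atm-1 at 1.5, 6, 12 and 24 h.

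The authors deposited log2 expression values per probe set, made with GCOS 1.2 followed by RMA in the affy package, per the submitters' processing notes. The RMA settings, and whether all arrays were normalised together, are not stated in the labels. The values were used as deposited, with no further normalisation. Array medians ran from 5.73 to 5.98, replicates correlated at 0.990 to 0.997 across probe sets, and 0 of 946 array pairs were identical. The number of arrays limits the precision.

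Of 22810 probe sets, 64 controls were left out. The platform annotation supplied gave 1 gene for 13513 of the remaining 22746 probe sets, several genes for 503, and none for 8730, which are unnamed here. Of the entries with 1 gene, 13436 matched the gene table (assembly TAIR10.1, used for names only) by gene ID, and 77 kept the annotation name. Where a gene had several probe sets, as 147 genes did, the one with the highest mean over all arrays stood for it, which left 13355 genes tested. A locus code is given for a gene without a symbol. ATM itself, BRCA1, CYCB1;1, SMR7, CCA1 and TOC1, which were to be named in every case, have no probe set with a single gene in this annotation, so the genotype labels could not be checked on the mutated gene.

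All arrays were fitted in 1 group-means model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes without trend, 22 residual and 7.82 prior degrees of freedom). Each comparison was adjusted by Benjamini-Hochberg over the 13355 genes, and a gene was called at an adjusted p under 0.05. Irradiated groups were compared with the unirradiated group of the same genotype, of day 1 up to 12 h and of day 2 at 24 h. ATM dependence is the change in WT minus the change in atm-1 at the same time, so a positive value means a larger rise, or a smaller fall, in WT. HZE and gamma were also compared directly in WT at each time, and at nearly matched clock times (HZE 1.5 h with gamma 6 h, HZE 6 h with gamma 12 h). Unirradiated atm-1 was compared with WT over both days, and day 2 with day 1 over both genotypes. Changes are log2 values with the standard error (SE) of the model.

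The comparisons, the controls, the tests, a set of 20 gene lists and the rule for naming genes were chosen before the data were examined. Only 4 of those lists had at least 3 measured members: G2/M cell cycle (Aurora kinases), histones, heat shock, and cold and dehydration. A further 16 lists were written from the annotation after it had been read and before any comparison was fitted: repair and recombination, replication and chromatin, mitosis, rapid stress, heat chaperones, cold and LEA proteins, branched-chain amino acid breakdown, nuclear photosynthesis, autophagy, stomatal lineage, root, seed, expansin and XTH, UGT, GST, and plastid-encoded genes. These lists share members (the 3 Aurora kinases with mitosis, the 5 histones with replication and chromatin). Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists and times of a family (WT gamma, for example), and again with an estimated correlation. Of 205 list calls, 44 held with the estimated correlation.

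For each comparison the genes named are those called with both irradiated replicates beyond both control replicates, ranked by log2 change: 10 highest and 5 lowest at 1.5 h, 5 and 5 at 24 h, and 3 and 3 at other times. ATM dependence followed the same ranks without the replicate condition, and direct and unirradiated comparisons gave 5 and 5. Up to 4 members per list with the largest absolute change and the 10 genes with the largest mean change of both radiations were also named, and a named gene is followed across the other comparisons. Shared calls were set beside independent lists and 20 simulations in which unchanged groups shared the control arrays.

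The model was tested on simulated data with 200 changed genes among 13355. In the simulated WT gamma 1.5 h comparison, 86% of 1.5-fold changes and 100% of 2-fold changes were recovered, and 17 unchanged genes were called. In simulated ATM dependence at gamma 1.5 h, 36% of 1.5-fold and 86% of 2-fold changes were recovered, and 10 unchanged genes were called.

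The alternatives tried were a replicate block, unirradiated arrays of both days as control, leaving out genes with a mean log2 value under 5, cyclic loess, eBayes with trend and robust hyperparameters, fewer arrays sharing the spread, the probe set with the lowest mean, leaving out each array in turn (the lone array left is assumed to vary like the other groups), controls split by day for shared calls, and the estimated correlation. Removal of 1 array with a low median (replicate 1 of atm-1 at gamma 6 h) was added after the data were seen. Across the 18 pairs of an irradiated group and its control, correlations of replicate differences ran from -0.0997 to 0.173, so these groups were not paired by replicate number. Over all 231 pairs of groups the highest was 0.239, with 40 over 0.1 and 19 under -0.1. Pairing among other groups, such as by HZE run, is therefore not excluded. Figures were drawn with matplotlib 3.10.9, and tables prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.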

Results

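The data are messenger RNA levels, as log2 expression, in whole Arabidopsis seedlings on 44 arrays, with 2 arrays in each of 22 groups. WT and atm-1, a mutant of the kinase ATM that starts the response to DNA double-strand breaks, received 100 Gy of gamma rays or 30 Gy of HZE, which are accelerated iron nuclei that leave dense tracks of damage. WT was sampled at 1.5, 3, 6, 12 and 24 h and atm-1 at 1.5, 6, 12 and 24 h after each radiation, beside unirradiated seedlings of both genotypes on day 1 and day 2. Seedlings of the 24 h groups and the day 2 controls were 6 days old and all others 5 days old. The HZE 12 h groups were sampled at 1:09 am on day 2 and compared with day 1 controls. Day 1 controls were sampled at 10:45 am and day 2 controls at 9:15 am. Gamma groups at 1.5, 3 and 24 h were sampled near those times, at 10:10, 11:40 and 8:40 am. Gamma groups at 6 and 12 h (2:55 and 8:40 pm) and all HZE groups were sampled hours away from their controls. Differences of these groups from controls hold radiation and time of day together. Clock time also differed between the radiations at the same time after irradiation. Differences between the genotypes at the same time after the same radiation compare plants sampled at the same clock time. Values below are log2 changes between groups of 2 arrays. The division of called genes into higher and lower depends on scaling, since the larger direction turned in 15 of 35 comparisons after cyclic loess.

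The comparison of gamma-irradiated WT with its control asks which genes respond to radiation and when. At 1.5 h the genes with the largest rise were AT5G23910, a kinesin-like motor protein gene, by log2 5.04 (SE 0.19, adjusted p 7.54e-19), AT5G11460 by 4.31, AT2G45460, which encodes a protein with a phosphopeptide-binding FHA domain, by nearly as much, and AT5G60250, a zinc finger gene, by 4.17. ATMND1, which acts in meiotic recombination, rose by log2 3.56 (SE 0.16, adjusted p 5.75e-17), and AT2G47680, AT5G67460, AT5G48020, AT3G45730 and AT3G42860 rose by 3.49 to 3.92. AT1G72200 fell by log2 2.43 (SE 0.19), AT3G19680 by 2.31 and AT4G01330 by 2.30. EXPA8, an expansin that loosens cell walls, fell by 2.43 (SE 0.43, adjusted p 9.48e-05). In all, 1108 genes were higher and 1181 lower, of which 192 and 207 changed at least 2-fold. The total of 2289 fell to 1343 without WT gamma 1.5 h replicate 2 and to 1432 without WT control day 1 replicate 1, and was 3718 with controls of both days. At 3 h, AT5G23910 stood at log2 5.10, AT2G47680 at 4.57 and AT4G22960 at 4.40, while the mitotic chromosome protein gene 3xHMG-box2 fell by 2.81 (SE 0.21). At that time 973 genes were higher and 1219 lower, a total of 2192 that fell to 1310 without WT gamma 3 h replicate 2 and to 1405 without WT control day 1 replicate 1.

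After gamma in WT some genes of this early set still led at 6 h, while at 12 and 24 h the leading genes were mostly others. At 6 h AT4G22960 was still higher by log2 4.37 and AT2G47680 by 3.87, among 1576 genes higher and 1863 lower. At 12 h AT3G62550, a gene of the universal stress protein family, rose by log2 6.57, AT4G34950 by 5.78 and AT4G30650 by 5.75. AT1G55960 fell by log2 4.84 and AT1G65490 by 4.80 at 12 h, and 1813 genes were higher and 1961 lower. At 24 h AT2G27420 rose by log2 5.46, TBL26 by 4.86 and AT1G73600 by 4.19. AT2G15960 fell at 24 h by log2 4.17, the clock-regulated CCL by 3.67 and AKINBETA1, a subunit of the energy-sensing SnRK1 kinase, by 3.38. The day 2 controls used at 24 h themselves differed from the day 1 controls. Over both genotypes the difference was log2 2.58 for AT2G15960, 2.23 for CCL and -2.15 for AT1G73600, so the size of these 24 h changes depends on the control day. At 24 h 1884 genes were higher and 2330 lower. The same genes moved alike in atm-1 at 24 h, where AT2G27420 rose by log2 5.49 and TBL26 by 4.02, and AT2G15960 fell by 3.26, CCL by 3.42 and AKINBETA1 by 3.12.

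Among gene lists after gamma in WT, the Aurora kinases of mitosis (AUR1, AUR2 and AUR3) fell together. At 3, 6 and 12 h, 3 of 3 were lower over all genes and also adjusted over the list alone, with list medians of log2 -1.67, -1.82 and -1.66 (adjusted p = 0.0208, 0.0233 and 0.0233 with an estimated correlation). The call of AUR3 ended at 3 h without WT gamma 3 h replicate 2 or either WT control of day 1, and at 6 h without WT gamma 6 h replicate 1 or WT control day 1 replicate 1. Repair and recombination genes were higher as a list at 1.5 h (4 higher and 1 lower of 21, median log2 0.19, adjusted p = 0.0184, but adjusted p = 0.217 with an estimated correlation). DNA ligase gene ATLIG4, for end joining, rose by log2 0.67, a call that ended without WT control day 1 replicate 1. Expansin and XTH genes, which remodel cell walls, were lower at 1.5 h (10 of 27, median log2 -0.44, adjusted p = 0.0681 with an estimated correlation), as were root genes (3 of 5, median -0.73, adjusted p = 0.239 with an estimated correlation). Plastid-encoded genes were higher at 3 h (21 higher and 2 lower of 62, median log2 0.17, adjusted p = 0.326 with an estimated correlation), and stomatal lineage genes were lower (2 of 3, median -0.35, adjusted p = 0.161 with an estimated correlation). Autophagy genes were higher at 3 h (4 of 10, median log2 0.44, adjusted p = 0.255 with an estimated correlation) and 6 h (8 of 10, median 0.65, adjusted p = 0.161 with an estimated correlation). At 24 h they were lower (8 of 10, median log2 -0.75, adjusted p = 0.159 with an estimated correlation), and so were nuclear photosynthesis genes (11 of 19, median -0.34, adjusted p = 0.246 with an estimated correlation). The autophagy list stood higher in the unirradiated day 2 controls than in those of day 1 by a median of log2 0.55, so its fall at 24 h depends on the control day.

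More genes were called after HZE than after gamma in WT at 1.5 and 3 h, led by genes that gamma moved less at those hours. The HZE groups were sampled at 2:39 and 4:09 pm, the gamma groups at 10:10 and 11:40 am. Their shared controls were sampled at 10:45 am, so the larger counts hold time of day as well as radiation and dose. At 1.5 h AT4G25580 rose by log2 6.63 (SE 0.27), AT1G19530 by 6.63 (SE 0.49), AT3G62550 by 6.04 (SE 0.18) and AT4G37220 by 5.69, while AT5G23910 rose by 5.07 (SE 0.19, adjusted p 2.59e-19), close to its rise after gamma. GSTU20, a glutathione transferase gene, fell by log2 3.95 (SE 0.30, adjusted p 2.3e-12), BCAT4, of glucosinolate chain elongation, by 3.94 (SE 0.67), and AT1G60590 by 4.27. At 1.5 h 2796 genes were higher and 2754 lower, of which 797 and 839 changed at least 2-fold, and at 3 h 3129 were higher and 2962 lower. At 3 h AT4G25580 stood at log2 7.39 and GSTU20 at -5.83. All 10 measured genes of branched-chain amino acid breakdown, which feeds respiration when sugar is short, were higher, with medians of log2 2.85 at 1.5 h and 3.14 at 3 h (adjusted p = 0.048 and 0.048 with an estimated correlation). Among them MCCA and MCCB, of methylcrotonyl-CoA carboxylase, rose by log2 3.92 and 3.46 at 1.5 h and isovaleryl-CoA dehydrogenase gene IVD by 3.72. All 10 autophagy genes were higher at 1.5 h (median log2 1.02, adjusted p = 0.0977 with an estimated correlation).

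At 6 h after HZE the rapid stress genes stood out in WT, and at 24 h fewer genes differed from the day 2 control. The zinc finger stress gene STZ rose by log2 5.39 at 6 h (SE 0.46, adjusted p 6.58e-11), AT4G27652 by 5.46, and 9 of 12 rapid stress genes were higher (median 2.02, adjusted p = 0.048 with an estimated correlation). At 6 h 1884 genes were higher and 2342 lower, and at 12 h 1816 were higher and 2060 lower, with AT3G62550 up by log2 6.75, AT4G29780 up by 4.95 and AT1G55960 down by 4.87. At 24 h AT3G45730 was still higher by log2 3.56, AT5G60250 by 3.24, AT3G02840 by 2.85 and AT4G22960 by 2.75. The 319 genes higher and 161 lower at 24 h, 480 in total, became 215 without WT HZE 24 h replicate 1, 309 without WT control day 2 replicate 1 and 224 without WT control day 2 replicate 2. With controls of both days the total was 2043. Seed genes were lower at 24 h (2 of 4, median log2 -0.62, adjusted p = 0.211 with an estimated correlation).

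Both radiations raised AT5G23910, AT3G45730, AT5G11460, AT2G45460, AT2G47680, AT3G42860, ATMND1, AT5G48020 and AT2G18600 by at least log2 3.29 in WT at 1.5 h. At 1.5, 3, 6, 12 and 24 h, 949, 1283, 2032, 2206 and 243 genes were called in the same direction after both, and 650, 394, 130, 102 and 40 in opposite directions. Both lists share control arrays. At an unadjusted p of 0.05, 1486 genes were shared at 1.5 h, against 134 on average in 20 simulations without effects and with shared controls. With no changed genes in them, the simulations show only what shared controls add, and cannot tell radiation from time of day. At 6 and 12 h both radiations were sampled hours after the morning controls, so shared calls there also hold time of day. Independent lists of the same lengths would share 232 higher and 244 lower genes at 1.5 h, against 437 and 512 observed. No such number was computed for opposite directions, where 650 genes were called at 1.5 h. The excess in the same direction therefore does not by itself show a common response. With the controls split by day, gamma against day 1 and HZE against day 2 at every time, 811, 1017, 1307, 1508 and 229 genes were shared. Control day and seedling age then differ between the radiations too, so the lower totals do not show the effect of separate control arrays alone. Shared genes with large changes included at 12 h AT3G62550 (log2 6.57 after gamma and 6.75 after HZE), CCL (4.88 and 4.91) and the cold-regulated COR15B (3.93 and 3.71), and at 24 h AT5G60250 (3.84 and 3.24).

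In atm-1 after gamma, the early rise of the leading WT genes was small or missing. At 1.5 h ATMND1 rose by log2 0.86, and the highest genes were PYE, a regulator of the iron response, by 2.67 (SE 0.18, adjusted p 1.36e-11), AT2G27420 by 2.53 and AT2G36630 by 2.46, while expansin-like EXLA1 fell by 2.01. UGT genes, which attach sugars to small molecules, were higher as a list (11 higher and 2 lower of 47, median log2 0.18, adjusted p = 0.021 with an estimated correlation). The 393 genes higher and 353 lower at 1.5 h, 746 in total, became 424 without atm-1 gamma 1.5 h replicate 1, 382 without its replicate 2, 430 without atm-1 control day 1 replicate 1 and 365 without its replicate 2, and 2107 with controls of both days. At 6 h AT3G62550 rose by log2 4.36, CCL by 3.66, and AT5G12110 fell by 2.35. The 1007 genes higher and 2060 lower, 3067 in total, became 1798 without atm-1 gamma 6 h replicate 1, 2013 without atm-1 control day 1 replicate 1 and 1987 without its replicate 2. At 12 h AT3G62550 rose by log2 6.36 among 1528 higher and 1612 lower genes, and at 24 h AT5G20790 rose by 5.39 among 1703 higher and 1974 lower.

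In atm-1 after HZE, AT3G62550 rose by log2 6.43 at 1.5 h, AT1G19530 by 5.95, CCL by 5.09 and PPDK, of pyruvate metabolism, by 3.96 (SE 0.25), and AT3G44970 fell by 3.82. The branched-chain breakdown genes again rose together (10 of 10, median log2 2.73, adjusted p = 0.0451 with an estimated correlation), with MCCA up by 3.77 and IVD by 3.47. At 1.5 h 2573 genes were higher and 2346 lower. At 6 h cold-regulated COR15B rose by log2 6.10 (SE 0.19) among 1624 higher and 1490 lower genes, and cold and LEA genes were higher as a list (4 higher and 1 lower of 9, median 0.22, adjusted p = 0.096 with an estimated correlation). At 12 h COR15B rose by log2 5.15 and THI2.2 fell by 4.26. At 12 h 1165 genes were higher and 1278 lower, a total of 2443 that fell to 1617 without atm-1 HZE 12 h replicate 1 and to 1625 without atm-1 control day 1 replicate 1. At 24 h STZ rose by log2 4.23 (SE 0.46, adjusted p 6.41e-07) and AT4G29780 by 4.16, among 151 higher and 56 lower genes, and this total of 207 became 62 without atm-1 HZE 24 h replicate 1 and 1581 with controls of both days, of which 728 were higher and 853 lower. Rapid stress genes were higher at 24 h in atm-1 (6 of 12, median log2 1.11, adjusted p = 0.0085 with an estimated correlation) and in WT (8 of 12, median 1.16, adjusted p = 0.0312 with an estimated correlation). The list was not called as ATM-dependent at that time.

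The genotype comparison after gamma asks which changes were larger or smaller in WT than in atm-1. At 1.5 h AT5G23910 rose more in WT by log2 4.48, AT5G60250 by 4.19, AT2G45460 by 3.76, AT3G45730 by 3.74, AT2G47680 by 3.38 and ATMND1 by 2.70. BHLH101, of the iron response, and AT3G62950 had lower changes in WT than in atm-1, by log2 -2.31 and -2.55. Of 192 genes that rose at least 2-fold in WT at 1.5 h, 131 depended on ATM, with a median change over the 192 of log2 1.36 in WT and 0.33 in atm-1. Of 207 genes that fell, 111 did. Both sets were picked by their change in WT, which also enters ATM dependence, so part of the gap between the medians is built in. Among genes that rose, 121 of 258 depended on ATM at 6 h, 22 of 336 at 12 h and 7 of 417 at 24 h. Of the 192, 258, 336 and 417 genes, 62, 172, 315 and 386 were also called higher in atm-1. A gene that depended on ATM could thus still rise in atm-1. The later sets may hold genes moved in both genotypes by time of day or control day. The shares therefore cannot tell whether ATM dependence itself faded. The 6 h calls also moved strongly with 1 array, as given below. At 6 h AT3G48770 differed by log2 3.19 and AT4G25330 by 3.00, and at 24 h AT5G60250 still did, by 2.15 (adjusted p 5.56e-08). Root hair expansin gene EXPA18 fell in WT relative to atm-1 at 1.5 h by log2 -1.26, and root genes did as a list (3 of 5, median -1.12, adjusted p = 0.0797 with an estimated correlation).

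ATM dependence after gamma was called for 321 genes in the positive and 433 in the negative direction at 1.5 h, 540 and 286 at 6 h, 60 and 111 at 12 h, and 15 and 12 at 24 h. The excess of positive calls at 6 h was smaller after cyclic loess, with 372 positive and 340 negative, and without the array with a low median, with 186 and 148. AT5G23910 led at 1.5 h and AT3G48770 at 6 h, and the number of calls moved with single arrays. The 754 calls at 1.5 h fell to 402 without WT gamma 1.5 h replicate 2, 488 without atm-1 gamma 1.5 h replicate 2, 500 without WT control day 1 replicate 1 and 433 without atm-1 control day 1 replicate 2. The 826 at 6 h became 443 and 430 without WT gamma 6 h replicates 1 and 2, 334 and 2298 without atm-1 gamma 6 h replicates 1 and 2, 418 without WT control day 1 replicate 1, and 463 and 425 without atm-1 control day 1 replicates 1 and 2. The 171 at 12 h became 108 and 91 without WT gamma 12 h replicates 1 and 2, 113 and 84 without atm-1 gamma 12 h replicates 1 and 2, 111 without WT control day 1 replicate 1, and 89 and 92 without atm-1 control day 1 replicates 1 and 2. The 27 at 24 h became 11 without WT gamma 24 h replicate 1, 8 without atm-1 gamma 24 h replicate 1, 46 and 10 without WT control day 2 replicates 1 and 2, and 55 without atm-1 control day 2 replicate 2, and 94 with controls of both days.

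**Figure D1:**
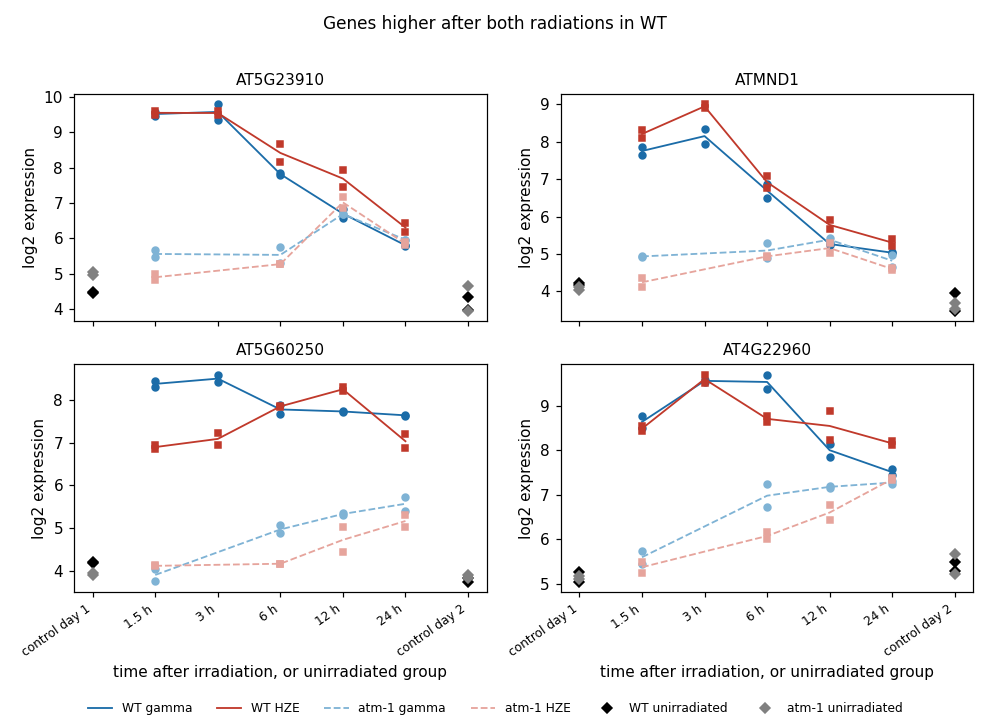
Log2 expression (y axis) of AT5G23910, ATMND1, AT5G60250 and AT4G22960 against hours after irradiation (x axis, with unirradiated controls of day 1 and day 2 at the ends), for WT (solid lines) and atm-1 (dashed lines) after gamma (blue) and HZE (red), with points for both replicates, lines through group means and diamonds for unirradiated seedlings. The WT lines of AT5G23910 lie log2 5.04 (gamma) and 5.07 (HZE) above the day 1 control at 1.5 h. The change in WT exceeds the change in atm-1 there by log2 4.48 and 5.17.

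After HZE the same genes depended on ATM at 1.5 h: AT5G23910 by log2 5.17 (SE 0.27, adjusted p 7.38e-15), AT5G11460 by 4.16, AT5G67460 by 3.99 and ATMND1 by 3.85. AT1G20180 depended on ATM at 1.5 h after HZE by log2 4.48 (SE 0.17, adjusted p 7.9e-18), and in WT it rose by 4.61, which was 4.32 more than after gamma. At 6 h AT3G02840 differed by log2 4.83 (SE 0.55), AT3G10930 by 4.22 and WRKY53 by 3.72, and 8 of 12 rapid stress genes were higher in WT (median 1.57, adjusted p = 0.0122 with an estimated correlation). Of genes that rose at least 2-fold in WT, 141 of 797 depended on ATM at 1.5 h, 230 of 487 at 6 h, 176 of 397 at 12 h and 6 of 105 at 24 h. In the same sets 695, 325, 269 and 68 genes were also called higher in atm-1. As after gamma, the sets were picked by their change in WT, which also enters ATM dependence. All HZE groups were sampled hours away from their controls, so the sets may hold genes moved in both genotypes by time of day. The shares therefore cannot be ranked against those after gamma. The calls numbered 243 positive and 115 negative at 1.5 h, 439 and 349 at 6 h, 362 and 264 at 12 h, and 9 and 8 at 24 h. The 358 at 1.5 h fell to 231 without atm-1 control day 1 replicate 2. The 626 at 12 h fell to 368 without atm-1 HZE 12 h replicate 2, 417 without WT control day 1 replicate 1 and 372 without atm-1 control day 1 replicate 2. The 17 at 24 h became 11 without WT HZE 24 h replicate 1, 8 and 9 without atm-1 HZE 24 h replicates 1 and 2, and 48 without atm-1 control day 2 replicate 2, and 43 with controls of both days. Genes dependent on ATM after both radiations in the same direction numbered 228, 261, 96 and 3 at 1.5, 6, 12 and 24 h, with 0, 3, 0 and 0 in opposite directions. With the controls split by day they numbered 150, 131, 57 and 3. At an unadjusted p of 0.05, 873 genes were shared at 1.5 h against 133 in simulations without effects, which show only what shared controls add.

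The division genes 3xHMG-box2 and AUR1 and the histone gene HTB2 fell after both radiations in WT, and at 12 h stood lower in WT than in atm-1 relative to the controls. 3xHMG-box2 and AUR1 also fell in atm-1 at 6 h, where the Aurora kinase list had medians of log2 -1.17 after gamma and -2.10 after HZE (adjusted p = 0.0577 and 0.0102 with an estimated correlation). The list was not called as ATM-dependent at 6 h after either radiation. 3xHMG-box2 fell by log2 2.72 after gamma and 2.74 after HZE at 6 h in WT, and at 12 h the genotypes differed by -2.05 and -2.93 (SE 0.30, adjusted p 8.99e-08 for HZE). AUR1 differed at 12 h by log2 -1.31 and -1.51 and HTB2 by -1.77 and -1.81. The Aurora kinase list was lower in WT at 12 h relative to atm-1 after gamma (median log2 -1.06, 2 of 3 lower, 3 adjusted over the list alone, adjusted p = 0.00167 with an estimated correlation) and after HZE (median -1.19, 3 of 3 by both counts, adjusted p = 0.00211 with an estimated correlation). Among these, AUR1 kept its call whichever array was left out. AUR2 lost its call after gamma without either WT gamma 12 h array, atm-1 gamma 12 h replicate 2, WT control day 1 replicate 2 or atm-1 control day 1 replicate 1, and after HZE without atm-1 HZE 12 h replicate 1. AUR3 lost its call after HZE without WT HZE 12 h replicate 1, atm-1 HZE 12 h replicate 1 or any control of day 1. Histones behaved alike (3 of 5 lower after gamma and 5 of 5 after HZE, the same adjusted over the list alone, medians log2 -0.58 and -1.04, adjusted p = 0.0165 and 0.00211 with an estimated correlation). The mitosis list, which includes the Aurora kinases, had medians of log2 -0.56 and -0.60 at 12 h. The replication and chromatin list, which includes the histones, had medians of -0.58 and -0.62. They are therefore not separate from the results above. PRL, a subunit of the replicative helicase, fell at 1.5 h in WT after gamma and, by log2 1.39, after HZE, and at 24 h after gamma it was higher than in the day 2 control by 1.12. In unirradiated seedlings the replication and chromatin list had a median of log2 -0.37 on day 2 relative to day 1. The rise of PRL at 24 h may therefore depend on the control day. At 24 h after gamma the replication and chromatin list was higher in WT relative to atm-1 (median log2 0.42, adjusted p = 0.00779 with an estimated correlation).

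**Figure D2:**
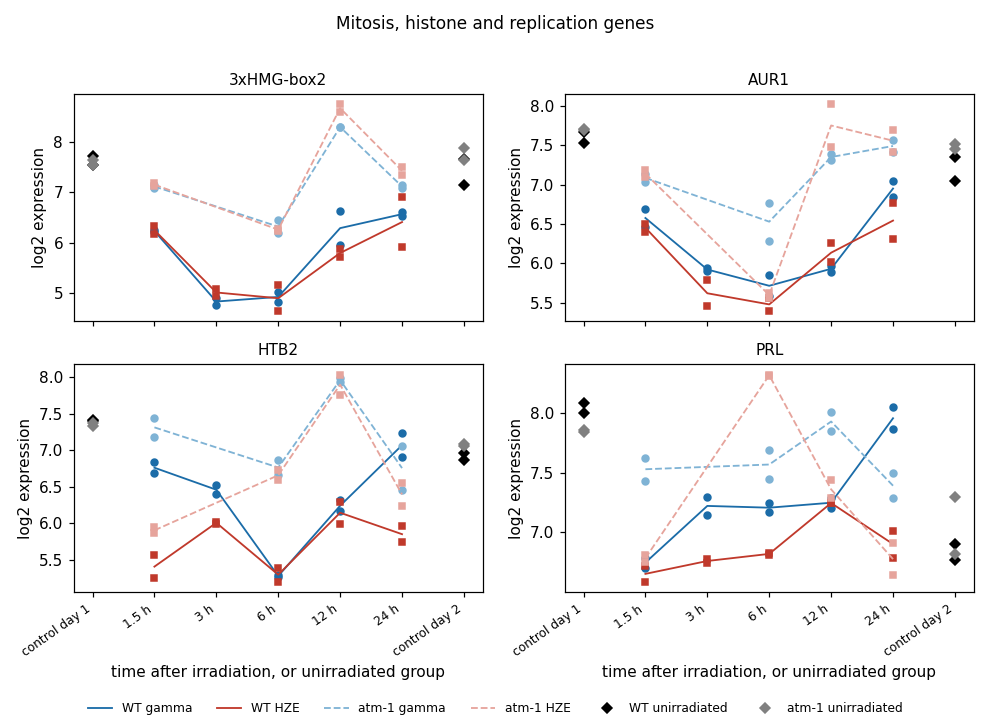
Log2 expression (y axis) of 3xHMG-box2, AUR1, HTB2 and PRL against hours after irradiation (x axis, with unirradiated controls of day 1 and day 2 at the ends), for WT (solid lines) and atm-1 (dashed lines) after gamma (blue) and HZE (red), with points for both replicates, lines through group means and diamonds for unirradiated seedlings. At 12 h the atm-1 lines lie above the WT lines. For 3xHMG-box2 the change in WT minus the change in atm-1 is log2 -2.05 (gamma) and -2.93 (HZE).

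The radiations were also compared directly in WT at the same time after irradiation. At 1.5 h AT3G62550 was higher after HZE by log2 7.33, CCL by 6.70 and AT1G19530 by 6.53, and AT5G42760 was lower by -6.04 and AT2G27420 by -5.74. At 6 h WRKY53 was higher after HZE by log2 4.47 and COR15B by 4.47, and BCAT4 was lower by -3.03. At 12 h STZ was higher by log2 5.40 and calmodulin-like CML38 by 4.47, clock gene GI was lower by -3.26, and rapid stress genes were higher (9 of 12, median 2.30, adjusted p = 0.0337 with an estimated correlation). At 24 h CCL was higher by log2 4.06 and TBL26 lower by -4.86. From 1.5 to 24 h, 2776, 2948, 1567, 1186 and 2341 genes were higher and 2763, 2677, 1491, 1316 and 1891 lower. At 6 h cold and dehydration genes were higher after HZE (2 of 3, also 2 adjusted over the list alone, median log2 1.21, adjusted p = 0.0337 with an estimated correlation), heat chaperones were higher (9 of 13, median 0.93, adjusted p = 0.0337 with an estimated correlation), and GST genes were lower (6 of 14, median -0.27, adjusted p = 0.0623 with an estimated correlation).

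At nearly matched clock times some HZE-raised genes stayed apart from gamma and others came close to it. AT3G62550 and CCL, which led at equal hours, differed by log2 2.36 and 1.32 between HZE 1.5 h and gamma 6 h, and were not called between HZE 6 h and gamma 12 h (log2 -0.22 and 0.17). HZE 1.5 h minus gamma 6 h gave log2 5.72 for AT4G25580, 5.39 (SE 0.27) for MCCA and -4.93 for AT1G73600, with 2727 genes higher and 2540 lower, and 9 of 10 branched-chain breakdown genes were higher (median 3.11, adjusted p = 0.041 with an estimated correlation). The autophagy list came closer, with a median difference of log2 0.29 between these groups against 1.09 between HZE and gamma at 1.5 h. HZE 6 h minus gamma 12 h gave log2 6.46 for AT4G29780, 5.88 (SE 0.46) for STZ and -3.49 for BCAT4, with 1443 genes higher and 1602 lower. Here 10 of 12 rapid stress genes were higher (median log2 2.57, adjusted p = 0.0102 with an estimated correlation), GI did not differ (-0.01), and heat shock genes were higher as a list (1 of 4, 2 adjusted over the list alone, median 0.41, adjusted p = 0.0924 with an estimated correlation). These pairs differ in hours since irradiation and in dose as well as in radiation.

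**Figure D3:**
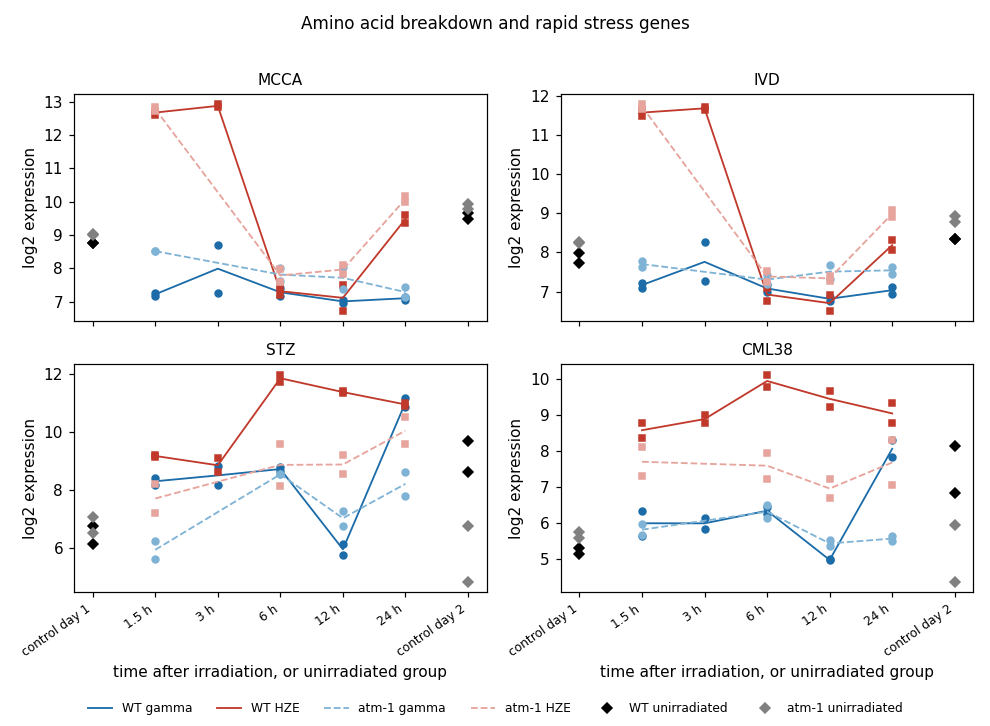
Log2 expression (y axis) of MCCA, IVD, STZ and CML38 against hours after irradiation (x axis, with unirradiated controls of day 1 and day 2 at the ends), for WT (solid lines) and atm-1 (dashed lines) after gamma (blue) and HZE (red), with points for both replicates, lines through group means and diamonds for unirradiated seedlings. At 1.5 h after HZE MCCA lies above the day 1 control by log2 3.92 in WT and 3.77 in atm-1, and STZ rose by 5.39 in WT at 6 h.

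Without irradiation, few genes were called between atm-1 and WT. AT1G47400 was higher in atm-1 by log2 1.26 (SE 0.20, adjusted p 0.000571), and AT2G16005 was lower by -0.97 and calmodulin-like CML23 by -0.95. STZ was lower in unirradiated atm-1 by log2 -1.49 (SE 0.33, adjusted p 0.0142). That call ended with trend and robust eBayes, with fewer arrays sharing the spread, and without WT control day 1 replicate 1, WT control day 2 replicate 1 or replicate 2 of either atm-1 control. Rapid stress genes were lower in atm-1 as a list (2 of 12, median log2 -0.45, adjusted p = 0.139 with an estimated correlation). In all 60 genes were higher and 112 lower, and this total of 172 became 54 without WT control day 1 replicate 1, 75 without WT control day 2 replicate 2, 45 without atm-1 control day 1 replicate 2 and 94 without atm-1 control day 2 replicate 1. Day 2 differed from day 1 far more, with 1963 genes higher and 1705 lower, among them AT2G15960 by log2 2.58, AT3G62550 by 2.57, CCL by 2.23 and AT3G44970 by -3.26.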

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

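The tests below were chosen after the results were seen, except the one that regroups the unirradiated arrays by genotype.

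ATM-dependent genes, among them AT5G23910 after both radiations, were set aside for a closer look because the genotypes differed in their change. They numbered 754, 826, 171 and 27 after gamma and 358, 788, 626 and 17 after HZE, at 1.5, 6, 12 and 24 h. Between the radiations in WT, 5539, 5625, 3058, 2502 and 4232 genes differed at 1.5, 3, 6, 12 and 24 h, with AT3G62550 and CCL at the head at 1.5 h. Division and replication lists differed between genotypes 12 h after gamma, with medians of log2 -1.06 for Aurora kinases, -0.58 for histones, -0.58 for replication and chromatin and -0.56 for mitosis. At 12 h after HZE these medians were log2 -1.19, -1.04, -0.62 and -0.60. The mitosis list includes the Aurora kinases, and the replication and chromatin list includes the histones, so these are not separate results. Replication and chromatin also differed 24 h after gamma (0.42) and 6 h after HZE (-0.88), and Aurora kinases (-0.69) and mitosis (-0.29) 24 h after HZE. Rapid stress genes such as STZ and WRKY53 differed between genotypes after HZE by a median of log2 1.57 at 6 h and 1.22 at 12 h. Between the radiations, medians were log2 3.04 for branched-chain breakdown at 1.5 h, 1.21 for cold and dehydration and 0.93 for heat chaperones at 6 h, and 2.30 for rapid stress at 12 h.

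The 9233 probe sets without a single annotated gene were fitted on their own after the data had been seen. Their calls numbered 2150, 4809, 853 and 398 in WT gamma 1.5 h, WT HZE 1.5 h, ATM dependence at gamma 1.5 h and ATM dependence at HZE 1.5 h, in that order. These were 23.3, 52.1, 9.2 and 4.3% of those probe sets, against 17.1, 41.6, 5.6 and 2.7% of the genes tested. Probe sets without a single gene therefore also changed, and in these comparisons a larger share of them was called.

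Branched-chain breakdown genes such as MCCA and IVD rose at 1.5 h after HZE in both genotypes. Time of day argues poorly as the cause, since the list median was log2 3.11 against gamma-irradiated plants of nearly the same clock time. Normalisation of arrays with lower medians does too, since the median was log2 2.79 after cyclic loess. The change did not need ATM (median dependence log2 0.14), which could fit either the radiation itself or the handling of the HZE plants, such as the move between facilities. No unirradiated plants handled like the HZE plants are among the groups, so this stays open.

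Rapid stress genes had a larger change in WT than in atm-1 at 6 h after HZE. Both genotypes were sampled at the same clock time, so the design of this comparison holds time of day equal. The median difference was log2 1.57, and the lowest with any 1 array left out was 1.24, so no single array made it. These genes also react to touch and transport, and unirradiated groups differed by a median of up to log2 0.68. Whether plates varied in such handling might be told only with more plates per group, so this stays open.

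In atm-1 at 6 h after gamma most called genes were lower, with 32.8% higher. After cyclic loess 49.8% were higher, and without replicate 1, whose array median of 5.73 was the lowest, 43.0% were. The excess of lower genes could therefore come from the normalisation of that array, and the named genes of that comparison kept their direction.

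Regrouping the 8 unirradiated arrays in all 35 ways into a pair of groups of 4 compared the genotype and day differences with other groupings. By genotype 3 genes were called, and 2 of the 35 groupings called as many, the other being the split by day with 2896. All remaining groupings called 0 genes. Since the split by day always counts, 2 of 35 was the lowest number this test could give. It therefore cannot decide whether chance made the genotype difference. The 172 genes called between genotypes come from the model that holds day constant. The split by day, with CCL and AT3G62550 among its genes, was matched by 1 of 35 groupings, itself, and the highest other grouping called 3 genes.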

How the results depend on the processing

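The numbers of genes called stayed within 1.5-fold under a replicate block, cyclic loess, trend and robust eBayes, fewer arrays sharing the spread, leaving out genes under a mean of 5, and the lowest-mean probe set. Cyclic loess turned the larger direction in 15 of 35 comparisons, for example to 2170 higher and 2066 lower in WT gamma 24 h, 2149 and 1898 in WT HZE 12 h, and 1990 and 1747 in atm-1 gamma 24 h. With 2 arrays per group, precision is limited, and where a result moved the cause was not tested. With unirradiated arrays of both days as control, 3718 genes were called in WT gamma 1.5 h, 2043 in WT HZE 24 h, 2107 in atm-1 gamma 1.5 h, 1581 in atm-1 HZE 24 h, and 94 and 43 for ATM dependence at 24 h after gamma and HZE. That control also reversed the heat chaperone list in WT HZE 24 h (median log2 0.049, adjusted p 0.929), PRL in atm-1 gamma 24 h (log2 -0.063) and CML38 in WT gamma 6 h (log2 -0.015). Without the array with a low median, 1798 genes were called in atm-1 gamma 6 h, 334 for ATM dependence at gamma 6 h and 27 at HZE 24 h. With controls split by day, 1307 genes were shared at 6 h. Of 205 list calls 44 held with the estimated correlation. In the same tests 212 were made with the block and 206 with the low array removed. With controls of both days 160 were made against 157 in the same 520 tests, and with dim genes left out 164 against 199 in the same 595 tests. The lowest-mean probe set reversed AT4G32700 in WT gamma 24 h (log2 -0.076). Leaving out WT gamma 12 h replicate 2 reversed ndhH in WT HZE 6 h minus gamma 12 h (log2 -0.091, and log2 1.90 without replicate 1), and leaving out WT control day 2 replicate 2 reversed PAP85 in WT gamma 24 h (log2 0.074, and log2 -2.80 without replicate 1). With 1 array left out, calls ran from 1343 to 2006 in WT gamma 1.5 h, 1310 to 1944 at 3 h, 365 to 430 in atm-1 gamma 1.5 h, 1798 to 3949 at 6 h, 215 to 321 in WT HZE 24 h, 1617 to 1683 in atm-1 HZE 12 h and 62 to 222 at 24 h. ATM dependence ran from 402 to 875, 334 to 2298, 84 to 138 and 8 to 55 after gamma, and 231 to 306, 526 to 696, 368 to 522 and 8 to 48 after HZE, and the unirradiated genotype difference from 45 to 178.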

Other observations

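STOMAGEN, which promotes stomata, fell by log2 1.28 in WT at 6 h after gamma and by 0.63 after HZE. UGT78D1 and UGT78D2, which glycosylate flavonols, rose by log2 2.63 and 2.60 in WT at 24 h after gamma, and UGT78D1 fell by 3.12 at 1.5 h after HZE. The rises at 24 h may depend on the control day, and the fall after HZE holds time of day as well as radiation. AT2G28720, a histone gene, rose by log2 2.54 in WT and 2.84 in atm-1 at 12 h after gamma, while the histone gene HTB2 fell by 1.17 in WT. GI, a clock gene, was higher than in the morning controls by log2 2.89 at 12 h after gamma in WT and by 2.88 at 6 h after HZE, with no call of ATM dependence at any time. Those groups were sampled in the evening, at 8:40 and 7:24 pm, so the GI differences cannot tell radiation from time of day.

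Among lists chosen beforehand with fewer than 3 measured members, RAD9 and AT1G52530 of DNA damage control were called in no comparison, with changes of log2 0.09 and -0.09 in WT gamma 1.5 h. Jasmonate marker PDF1.2 changed by 0.16 and stem cell genes BBM and CLV3 by -0.10 and -0.02 in that comparison, none of them called. Flavonoid gene DFR fell by log2 1.26 at 1.5 h after HZE in WT, and photosynthesis gene LHCB4.1 fell by 0.69 at 24 h after gamma.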
